A study of Homo sapiens with 20 samples.

How the data were processed

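Total RNA from 20 samples of WPMY-1 cells, 5 for each combination of hairpin (Hic-5 or negative control) and treatment (TGFB or ethanol vehicle for 16 h), was labelled from 300 ng of RNA and read on Affymetrix Human Gene 1.0 ST arrays, per the labels' protocols. The dose of TGFB, scan dates and batches are not given in the sources used here. The authors deposited a table of log2 values with 31318 rows and 1 column per sample, made with RMA (background correction, quantile normalization and summary over probes), and limma is named as well, per the submitters' processing notes. Versions of these tools are not given in the sources used here. The values ran from 0.857 to 14.1 with 0 missing, the array medians lay between 5.36 and 5.43, and 0 value columns were left unused. Because RMA sets every array to the same distribution, a shift of all genes in a group would not be seen. Arrays carry no depth, so their number limits the precision.

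Each sample's group and replicate number came from its title. Rows were named through the platform's gene table, which listed 21207 of them: 19455 with 1 gene symbol and 1752 with several, and 10111 rows were not listed. The 11863 rows with no single gene entered no comparison and were tested apart. Where 768 genes had more than 1 row, the row with the highest mean over all arrays was used, which left 18414 genes, 16901 of them protein-coding. Symbols were looked up through the Entrez number in a RefSeq gene table (GRCh38.p14), which held 18386 of them and changed 0. No coordinates are printed, since the genome build of the array is not given in the sources used here. No 2 arrays of a group were copies: the smallest mean absolute difference was 0.19 log2 units. Repeat arrays of 1 RNA are not excluded.

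One model with a mean per group was fitted over all 20 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, so that the 4 groups shared 1 estimate of the spread. The 5 contrasts were taken from it: the Hic-5 hairpin against the control hairpin in vehicle and in TGFB, TGFB against vehicle in each line, and the difference of the TGFB effects. P-values are two-sided and were adjusted by Benjamini-Hochberg within a contrast, genes were called at an adjusted p under 0.05, and counts are also given for changes of at least 1.5-fold. Errors of differences are moderated standard errors over 5 against 5 arrays.

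The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The 28 lists were TGFB feedback and early targets, TGFB family ligands, receptors and SMADs, collagens, matrix glycoproteins, collagen-modifying and crosslinking enzymes, proteoglycans and hyaluronan, contractile and smooth muscle genes, focal adhesion and LIM-domain proteins, integrins, matrix proteases and their inhibitors, YAP and TEAD targets, cytokines and chemokines, interferon-stimulated genes, secreted growth factors, the WNT pathway, cell cycle, androgen and glucocorticoid receptors and their targets, sterol biosynthesis and uptake, unfolded protein response, hypoxia and glycolysis, p53 targets, NADPH oxidases and antioxidant defence, the NOTCH pathway, and epithelial, endothelial, leukocyte, pericyte and adipocyte markers. Each list was tested in each contrast with camera at its preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation. The rule named TGFB1I1 and its paralogs PXN and LPXN, the 10 largest rises and falls per contrast among called genes (in the 4 simple contrasts only where the groups did not overlap), up to 4 called members per list by p, and a list's member with the smallest p where none was called; the text names fewer of these, in order of size or p.

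The size of the TGFB response was compared over genes called for the mean of the TGFB effects, as the ratio of root mean squares, with a jackknife over arrays. The comparison of the hairpin effect with the TGFB effect shares the control vehicle arrays, so unchanged groups were simulated 50 times against them. After seeing the data, the 5 pairs of vehicle arrays were split in all 10 ways. Each gene's deviations from its group means gave the main component within groups. The same deviations were used to check whether replicate numbers pair the arrays. Between the vehicle groups 5 of 5 pairs of equal number correlated above 0.1 (from 0.138 to 0.873). Some pairs of unequal number did too (up to 0.526), so pairing by number is assumed here, not shown. What a number shares is not given in the sources used here. For no other 2 groups did more than 2 of 5 pairs pass 0.1.

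The fit was tested in 10 simulations with 200 of 18414 genes changed. For the hairpin effect in vehicle it recovered 62.8%, 94.0%, 98.6% and 99.8% of genes changed by 0.5, 1, 1.5 and 2 log2 units, with 5.41% of calls false. For the difference of TGFB effects it recovered 24.6%, 82.0%, 94.4% and 97.6%, with 3.46% false. A list of 25 genes shifted by 0.3 was called by camera in 10 of 10 simulations with either correlation, and 0 of 270 unchanged lists were.

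Alternatives were leaving out each array, a replicate block, array weights, an intensity trend with robust moderation, a fit of the 2 groups alone, cyclic loess, leaving out dim genes (11048 genes kept), the mean of a gene's rows, all deposited rows, and an estimated correlation for camera. Leaving out both vehicle arrays numbered 2, the component score as a covariate and a replicate block in the vehicle arrays were chosen after seeing the data.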

Results

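Gene expression was measured in WPMY-1 cells, an immortalised myofibroblast line from human prostate stroma, that carried either a short hairpin RNA against Hic-5 or a negative control hairpin. Hic-5 is the product of TGFB1I1, a LIM-domain adaptor of the paxillin family that sits at focal adhesions and is itself induced by TGFB. Cells spent 48 h in medium with 5% hormone-depleted serum, and TGFB or its ethanol vehicle was then given for 16 h. The design implies 4 simple comparisons, namely the effect of the Hic-5 hairpin in vehicle and in TGFB and the effect of TGFB in each hairpin line, and the test of whether the TGFB effect differed between the lines. Total RNA of 20 samples, 5 in each of the 4 combinations of hairpin and treatment, was read on Affymetrix Human Gene 1.0 ST arrays. The series describes the 5 samples of each kind as independent but does not say whether they came from separate cultures or days, so the p-values measure the spread between these samples. Each arm had 1 hairpin line, so the effect of losing Hic-5 and any other difference between the lines cannot be told apart.

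Signals are log2 values after RMA, and 18414 genes were tested. With 5 arrays per group the median standard error was 0.109 log2 units for a difference between groups and 0.154 for the difference of the TGFB effects. The table holds no detection calls, so a group mean below 5.3, the limit used for dim genes, is not shown to lie above background. This holds for 51 of 217 differences checked among those named below, and for 9 of them in every group compared: NTS and CD24 between the hairpin lines in both treatments, IDO1 in vehicle, ADAMTS5 in TGFB, COL8A1 and OAS2 after TGFB, and B3GALT1 in the difference. On 1 side it holds in vehicle for ANXA10, IFI44, IFI44L, GPAT3, OASL, TEK and RRAGD, and in TGFB for CEMIP, NRG1, OASL, IFI44, ANXA10, CYP24A1 and TEK. For the TGFB effect it holds on 1 side in the control line for NOX4, NPR3, TSPAN2, IL1B, KIT, GDF5, ACTC1, IFIT3, BMP4 and BMP6. In the Hic-5 line it does for NOX4, NPR3, TSPAN2, PGM2L1, ST6GAL2, PMEPA1, ACTC1, FBLN5, ITGB3, ITGA11, P4HA3, NEDD9, VCAM1, GPAT3 and IL1B, and so for the differences of PMEPA1, P4HA3 and VCAM1. Arrays of a group correlated at 0.976 to 0.993 across genes. A single component held 53.3% of the variance within groups, and control vehicle replicate 2 scored 54.8 on it and Hic-5 vehicle replicate 2 scored 46.0, against scores of -21.7 to -2.98 for the other vehicle arrays. The mean score of a group, with differences between groups kept in, was 5.84 ± 31.3 (SD, n = 5) in control vehicle, 3.08 ± 26.5 in Hic-5 vehicle, -6.50 ± 17.3 in control TGFB and -2.42 ± 12.3 in Hic-5 TGFB.

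**Figure D1:**
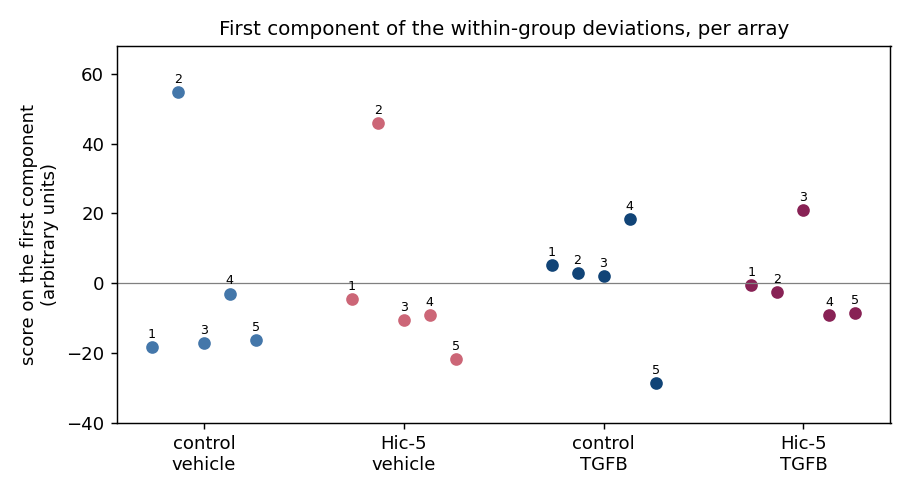
Score of each array on the main component of the deviations from the group means (y axis, arbitrary units) for the 4 groups of 5 arrays (x axis), with replicate numbers above the points. The vehicle arrays numbered 2 lie highest, at 54.8 in the control line and 46.0 in the Hic-5 line, and control TGFB replicate 5 lies lowest, at -28.6.

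The targeted gene was lower in the Hic-5 hairpin line in both treatments. TGFB1I1 (array row 7995206) averaged 7.96 ± 0.19 log2 units (SD, n = 5) in control vehicle, with single arrays at 7.90, 8.30, 7.79, 7.89 and 7.91, and 7.07 ± 0.19 in Hic-5 vehicle, with arrays at 7.14, 7.37, 6.98, 6.95 and 6.93. After TGFB it averaged 8.39 ± 0.34 in the control line, with arrays at 8.75, 8.28, 8.14, 8.74 and 8.01, and 7.56 ± 0.13 in the Hic-5 line, with arrays at 7.66, 7.41, 7.69, 7.62 and 7.42. The hairpin lowered it 1.85-fold in vehicle (log2 difference -0.88 ± 0.14 SE, adjusted p = 0.000493) and 1.78-fold in TGFB (-0.83 ± 0.14, adjusted p = 0.00112), and all 5 Hic-5 arrays lay below all 5 control arrays of the same treatment.

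TGFB1I1 was 0.43 ± 0.14 log2 units higher after TGFB in the control line, which did not pass the test (adjusted p = 0.0589). It passed without control vehicle replicate 2 (adjusted p = 0.0223), control TGFB replicate 3 (0.0445) or control TGFB replicate 5 (0.0197). In the Hic-5 line it rose by 0.48 ± 0.14 (adjusted p = 0.0272), and this call was lost without Hic-5 vehicle replicate 3 (adjusted p = 0.0677), 4 (0.0705) or 5 (0.0701), or without Hic-5 TGFB replicate 1 (0.0669), 3 (0.0672) or 4 (0.0607). The TGFB effects on TGFB1I1 differed by 0.06 ± 0.19 between the lines (adjusted p = 0.997). The paralog PXN, which encodes paxillin, differed by 0.06 and 0.19 between the hairpin lines in vehicle and TGFB (adjusted p = 0.877 and 0.361) and by 0.21 after TGFB in the control line (0.178, and 0.0326 with array weights). PXN rose by 0.34 after TGFB in the Hic-5 line (adjusted p = 0.0165), a call lost without Hic-5 TGFB replicate 1 (0.0563) and with the mean of the gene's array rows (0.304). LPXN, which encodes leupaxin, differed by -0.44 in vehicle and -0.52 in TGFB between the hairpin lines (adjusted p = 0.147 and 0.0813), passed in TGFB without control TGFB replicate 1 (0.0248) or Hic-5 TGFB replicate 4 (0.0260), and differed by -0.20 and -0.27 after TGFB in the control and Hic-5 lines (0.532 and 0.379). The TGFB effects of the lines differed by 0.13 for PXN and -0.08 for LPXN (adjusted p = 0.994 and 0.997).

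**Figure D2:**
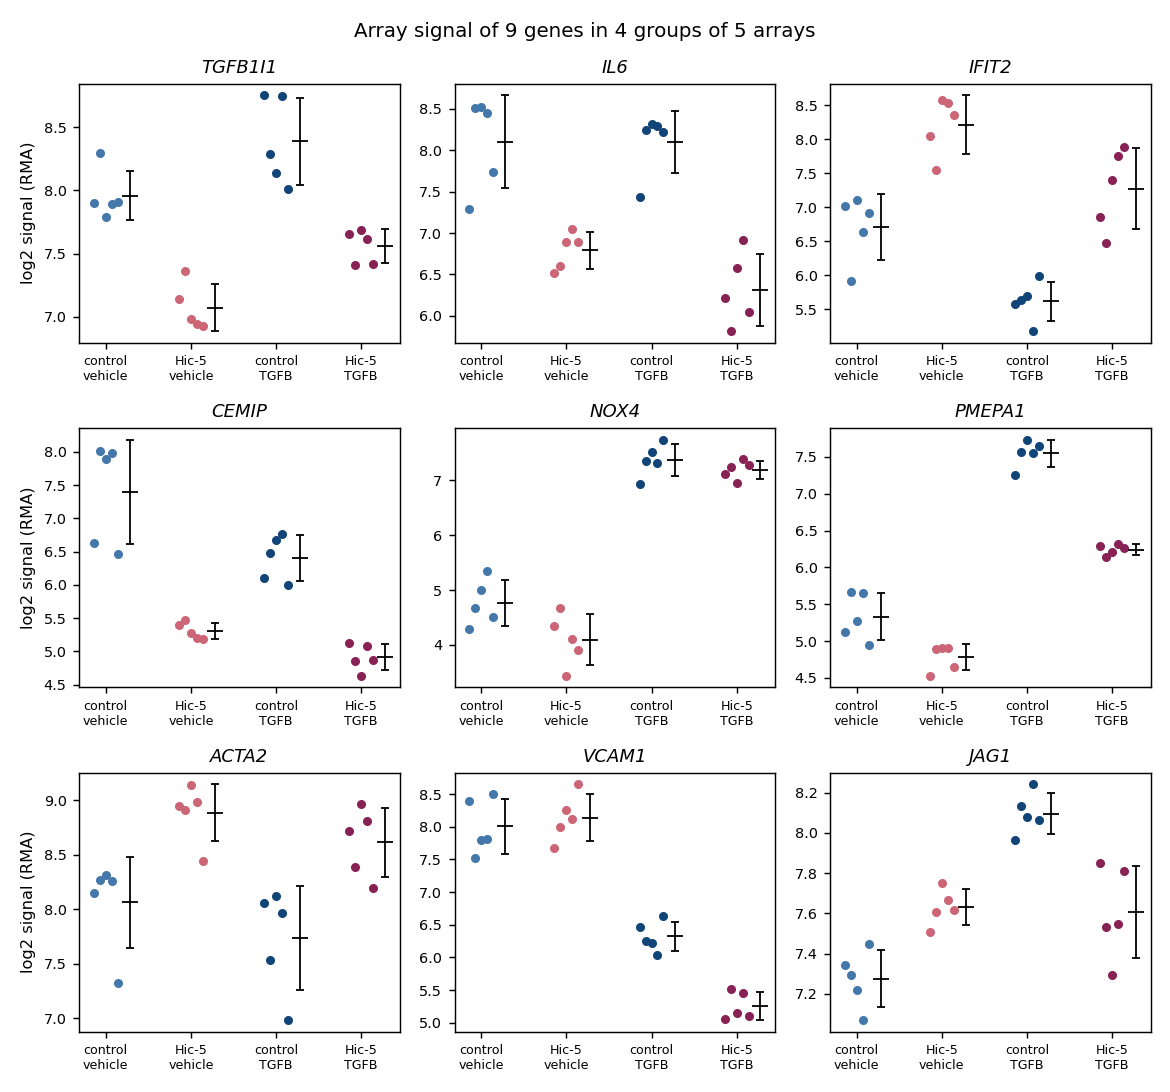
Log2 RMA signal (y axis) of 9 genes on each array (points) of the 4 groups of 5 (x axis), with the group mean and SD beside the points in black; the scales differ between panels. TGFB1I1 and IL6 are lower in the Hic-5 line in both treatments, NOX4 is higher after TGFB in both lines, and the TGFB effect on JAG1 is 0.82 in the control line and -0.02 in the Hic-5 line.

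Without added TGFB, the Hic-5 hairpin line differed from the control line in 598 genes, of which 196 were higher and 402 lower. By camera the lists of crosslinking enzymes, integrins and YAP targets shifted down and that of interferon-stimulated genes shifted up, with a preset and with an estimated correlation. Collagens, matrix glycoproteins and cytokines shifted down with the preset correlation, but adjusted p = 0.2, 0.0699 and 0.0781 with an estimated correlation. NTS, which encodes the neuropeptide neurotensin, had the largest rise, and CEMIP, which encodes a hyaluronan-degrading protein, was 4.25-fold lower. At a change of at least 1.5-fold there were 223 genes, 74 higher and 149 lower. Without control vehicle replicate 4 the number fell from 598 to 397, and in a fit of these 2 groups alone it was 341.

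The largest rises in vehicle, after NTS (2.45 ± 0.15, adjusted p = 4.14e-09), were those of ANXA10, an annexin (1.88 ± 0.18, 2.32e-06), the interferon-induced IFI44 (1.67 ± 0.29, 0.00135), and GPAT3, an enzyme of triglyceride synthesis (1.59 ± 0.17, 6.12e-06). IFIT2 and OASL, both interferon-induced, followed at 1.5 ± 0.26 (adjusted p = 0.00171) and 1.36 ± 0.17 (3.89e-05). RGS2, a regulator of G protein signalling, and IDO1, a tryptophan-degrading enzyme, rose by 1.34 ± 0.20 and 1.34 ± 0.21 (adjusted p = 0.000451 and 0.000489). CEMIP fell by 2.09 ± 0.25 (adjusted p = 3.34e-05), THBS1, the matrix protein thrombospondin 1 that can activate latent TGFB, by 1.65 ± 0.16 (2.24e-06), and the WNT ligand gene WNT5A by 1.51 ± 0.13 (8.76e-07). CD24, a cell surface glycoprotein, fell by 1.40 ± 0.19 (adjusted p = 0.000129), the matrix protease MMP3 by 1.33 ± 0.30 (0.0147) and PIEZO2, a mechanically gated cation channel, by 1.33 ± 0.12 (9.63e-07). IL6 fell by 1.31 ± 0.24 (adjusted p = 0.00232), RRAGD, a GTPase of lysosomal mTORC1 signalling, by 1.26 ± 0.11 (1.09e-06), the vasodilator peptide gene ADM by 1.20 ± 0.13 (1.14e-05) and the GDNF co-receptor gene GFRA1 by 1.20 ± 0.15 (6.05e-05). The MMP3 call was lost without control vehicle replicate 3 (adjusted p = 0.0502) or 4 (0.0574), without Hic-5 vehicle replicate 1 (0.0535) and in a fit of these 2 groups alone (0.0611).

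Of the 28 gene lists, 17 shifted in vehicle by camera with its preset correlation, 14 of them down, and 4 did with an estimated correlation. Of 17 collagen-modifying and crosslinking enzymes, 0 rose and 5 fell and 12 were not called, and 8 fell when adjusted over the list alone. The median was -0.332 (camera adjusted p = 2.66e-08, and 0.0355 with an estimated correlation). LOXL2 and LOX, lysyl oxidases that crosslink collagen, fell by 0.59 ± 0.10 and 0.57 ± 0.12 (adjusted p = 0.00132 and 0.00841). Among 25 matrix glycoproteins 8 fell, 1 rose and 16 were not called, with 11 down and 1 up adjusted over the list alone. The median was -0.123 (camera adjusted p = 9.13e-08, but adjusted p = 0.0699 with an estimated correlation). Besides THBS1, they included THBS2 (-1.0 ± 0.10, adjusted p = 4.69e-06), the matricellular CCN3 (-1.11 ± 0.13, 2.22e-05) and tenascin C, TNC (-1.16 ± 0.14, 4.95e-05). Collagens had 2 of 24 down, 0 up and 22 not called, against 12 down and 1 up adjusted over the list alone. The median was -0.27 (camera adjusted p = 5.43e-05, but adjusted p = 0.2 with an estimated correlation). The 2 were COL5A2 (-0.50 ± 0.12, adjusted p = 0.0204) and COL5A1 (-0.61 ± 0.15, 0.0255), chains of collagen V. Hic-5 vehicle replicate 2, which stood apart on the main component, had the highest mean of its group over the collagens and over the matrix glycoproteins. The COL5A2 call was lost without control vehicle replicate 2 (adjusted p = 0.0540) or 4 (0.0632), Hic-5 vehicle replicate 1 (0.0704) or both vehicle arrays numbered 2 (0.0573). For COL5A1 it was lost without control vehicle replicate 2 (0.0623) or 4 (0.0817), without Hic-5 vehicle replicate 1 (0.0707), 3 (0.0707), 4 (0.0606) or 5 (0.0674) and in a fit of the 2 groups alone (0.115).

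Proteoglycans and hyaluronan genes had 3 of 21 down, 0 up and 18 not called, with 4 down and 1 up adjusted over the list alone. The median was -0.0659 (camera adjusted p = 0.0367, but adjusted p = 0.0876 with an estimated correlation). They included CEMIP and the syndecan gene SDC2 (-0.53 ± 0.08, adjusted p = 0.000575). The list was no longer called without control vehicle replicate 2 (adjusted p = 0.0506), 3 (0.0743) or 5 (0.0865), Hic-5 vehicle replicate 2 (0.122) or 5 (0.0798), or both vehicle arrays numbered 2 (0.0866). Matrix proteases and their inhibitors had 5 of 26 down, 1 up and 20 not called, with 9 down and 3 up adjusted over the list alone. The median was -0.0918 (camera adjusted p = 0.0027, but adjusted p = 0.183 with an estimated correlation). The metalloproteases ADAM12 and ADAMTS12 fell by 0.69 ± 0.07 and 0.98 ± 0.11 (adjusted p = 9.42e-06 and 1.14e-05).

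Cytokines and chemokines had 8 of 27 genes down, 1 up and 18 not called, with 11 down and 1 up adjusted over the list alone. The median was -0.299 (camera adjusted p = 1.64e-08, but adjusted p = 0.0781 with an estimated correlation). CCL2, which attracts monocytes, fell by 1.16 ± 0.12 (adjusted p = 3.84e-06), IL1B by 0.90 ± 0.14 (0.00056), the chemokine gene CXCL12 by 0.77 ± 0.13 (0.00109) and IL11 by 0.86 ± 0.14 (0.00109). Interferon-stimulated genes went the other way, with 8 of 24 up, 0 down and 16 not called, and 10 up adjusted over the list alone. The median was 0.252 (camera adjusted p = 1.17e-08, and 0.0086 with an estimated correlation). IFI44L rose by 1.14 ± 0.21 (adjusted p = 0.0028), beside OASL, IFI44 and IFIT2.

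Of 18 YAP and TEAD targets, 5 fell, 0 rose and 13 were not called, with 7 down and 1 up adjusted over the list alone. The median was -0.17 (camera adjusted p = 5.43e-05, and 0.0355 with an estimated correlation). The receptor tyrosine kinase gene AXL fell by 0.55 ± 0.09 (adjusted p = 0.00101), ANKRD1 by 1.07 ± 0.18 (0.0012), and the matricellular genes CCN2 and CCN1 by 0.61 ± 0.12 and 0.50 ± 0.11 (0.00567 and 0.0147). Integrins had 5 of 16 down, 0 up and 11 not called, with 5 down and 1 up adjusted over the list alone. The median was -0.177 (camera adjusted p = 0.00132, and 0.0229 with an estimated correlation). They included ITGA5, a subunit of the fibronectin receptor (-0.53 ± 0.10, adjusted p = 0.00336), ITGB5 (-0.55 ± 0.11, 0.00567), ITGA3 (-0.54 ± 0.12, 0.0118) and ITGA7 (-0.44 ± 0.10, 0.0168). The ITGA7 call was lost without control vehicle replicate 4 (adjusted p = 0.0595) or Hic-5 vehicle replicate 1 (0.0557). Control vehicle replicate 2 had the lowest integrin mean of its group.

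Contractile and smooth muscle genes had 3 of 25 down, 2 up and 20 not called, with 8 down and 2 up adjusted over the list alone. The median was -0.116 (camera adjusted p = 0.00244, but adjusted p = 0.0876 with an estimated correlation). MYLK, the myosin light chain kinase, fell by 1.06 ± 0.07 (adjusted p = 2.28e-08) and CNN1, calponin, by 0.44 ± 0.11 (0.0272), while PDLIM5, a PDZ and LIM protein, rose by 0.66 ± 0.13 (0.00444). ACTA2, the smooth muscle actin used as a myofibroblast marker, rose by 0.82 ± 0.22 (adjusted p = 0.0376). The CNN1 call was lost without control vehicle replicate 2 (0.0751), 3 (0.0656) or 4 (0.0557), without Hic-5 vehicle replicate 3 (0.0635), 4 (0.0873) or 5 (0.0674), and in a fit of the 2 groups alone (0.0845). For ACTA2 it was lost without control vehicle replicate 1 (0.0587), 4 (0.0587) or 5 (0.0993), without Hic-5 vehicle replicate 1 (0.0849), 2 (0.0595), 3 (0.101) or 4 (0.0873), without both vehicle arrays numbered 2 (0.0503), in a fit of the 2 groups alone (0.0567) and with an intensity trend and robust moderation (0.0551). Focal adhesion and LIM-domain genes had 4 of 26 down, 2 up and 20 not called, with 8 down and 2 up adjusted over the list alone. The median was -0.103 (camera adjusted p = 0.00658, but adjusted p = 0.282 with an estimated correlation and 0.0506 without control vehicle replicate 2). TLN2, which links integrins to actin, fell by 0.72 ± 0.08 (adjusted p = 9.41e-06) and tensin 3, TNS3, by 0.52 ± 0.09 (0.00146), while TES, a LIM-domain protein, rose by 0.65 ± 0.12 (0.00306).

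TGFB feedback and early target genes had 4 of 23 down, 1 up and 18 not called in vehicle, with 5 down and 1 up adjusted over the list alone. The median was -0.105 (camera adjusted p = 0.00658, but adjusted p = 0.304 with an estimated correlation and 0.0827 without control vehicle replicate 2, which had the highest mean of its group over the list). LTBP2, of the latent TGFB binding protein family, fell by 0.67 ± 0.13 (adjusted p = 0.00433) and KLF10, a zinc finger factor induced early by TGFB, by 0.52 ± 0.11 (0.00576). TGFB family ligands, receptors and SMADs had 6 of 29 down, 0 up and 23 not called, with 7 down and 2 up adjusted over the list alone. The median was -0.0708 (camera adjusted p = 0.0153, but adjusted p = 0.0876 with an estimated correlation). FSTL1, a secreted glycoprotein, fell by 0.65 ± 0.08 (adjusted p = 9.13e-05) and CHRDL1, a BMP antagonist, by 0.84 ± 0.12 (0.000234). Unfolded protein response genes had 4 of 24 down, 0 up and 20 not called, with 5 down adjusted over the list alone. The median was -0.169 (camera adjusted p = 6.09e-06, but adjusted p = 0.0781 with an estimated correlation). The chaperone gene HYOU1 fell by 0.64 ± 0.10 (adjusted p = 0.00053) and PDIA6, a protein disulfide isomerase, by 0.31 ± 0.07 (0.0168). The PDIA6 call was lost without Hic-5 vehicle replicate 1 (0.0513) and without both vehicle arrays numbered 2 (0.0590). Hypoxia and glycolysis genes had ADM as the 1 of 23 that fell, 0 up and 22 not called, with 2 down adjusted over the list alone. The median was -0.172 (camera adjusted p = 5.43e-05, but adjusted p = 0.252 with an estimated correlation).

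The p53 target list shifted up in vehicle with 0 of its 21 genes called, in the whole test or adjusted over the list alone. The median was 0.165 (camera adjusted p = 0.00963, but adjusted p = 0.395 with an estimated correlation, 0.0569 without control vehicle replicate 2 and 0.0953 without control vehicle replicate 5). Endothelial markers had TEK, the angiopoietin receptor gene, as the 1 of 16 that rose (0.60 ± 0.16, adjusted p = 0.0410), 0 down and 15 not called, with the same counts adjusted over the list alone. The median was 0.0677 (camera adjusted p = 0.0359, but adjusted p = 0.395 with an estimated correlation). That list was no longer called without control vehicle replicate 1 (adjusted p = 0.118), 4 (0.0660) or 5 (0.0640), Hic-5 vehicle replicate 2 (0.276) or 4 (0.0842), with dim genes left out (0.548) or after cyclic loess (0.0660). The TEK call was lost without control vehicle replicate 1 (0.110), 4 (0.0870) or 5 (0.109), without Hic-5 vehicle replicate 1 (0.0503), 3 (0.0883), 4 (0.0736) or 5 (0.119), after cyclic loess (0.0624) and in a fit of the 2 groups alone (0.0877). Pericyte and mesenchymal progenitor markers went both ways, with 3 of 17 up, 3 down and 11 not called, 4 up and 4 down adjusted over the list alone, and camera adjusted p = 0.414. MCAM, a pericyte adhesion molecule, fell by 0.56 ± 0.08 (adjusted p = 0.000207) and PDGFRB by 0.66 ± 0.14 (0.00722, and 0.0761 in a fit of the 2 groups alone), while the mesenchymal transcription factor gene PRRX1 rose by 0.69 ± 0.12 (0.0015) and PDGFRA by 0.62 ± 0.12 (0.0036).

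The remaining 10 lists were not called in vehicle. Of 19 epithelial markers 0 were called (camera adjusted p = 0.794), of 17 leukocyte markers 0 (0.414), of 17 adipocyte markers 1 fell (0.756), and of 32 cell cycle genes 0 were called (0.436). Secreted growth factors had 2 up and 1 down of 27 (0.516), the WNT pathway 1 up and 3 down of 30 (0.113), and androgen and glucocorticoid receptors with their targets 1 up and 1 down of 19 (0.756). Sterol biosynthesis and uptake had 0 of 16 called (0.711), NADPH oxidases and antioxidant defence 1 up of 22 (0.414) and the NOTCH pathway 1 down of 16 (0.905). For the NOTCH pathway and the epithelial markers the median was above 0 while the mean and the test pointed down.

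**Figure D3:**
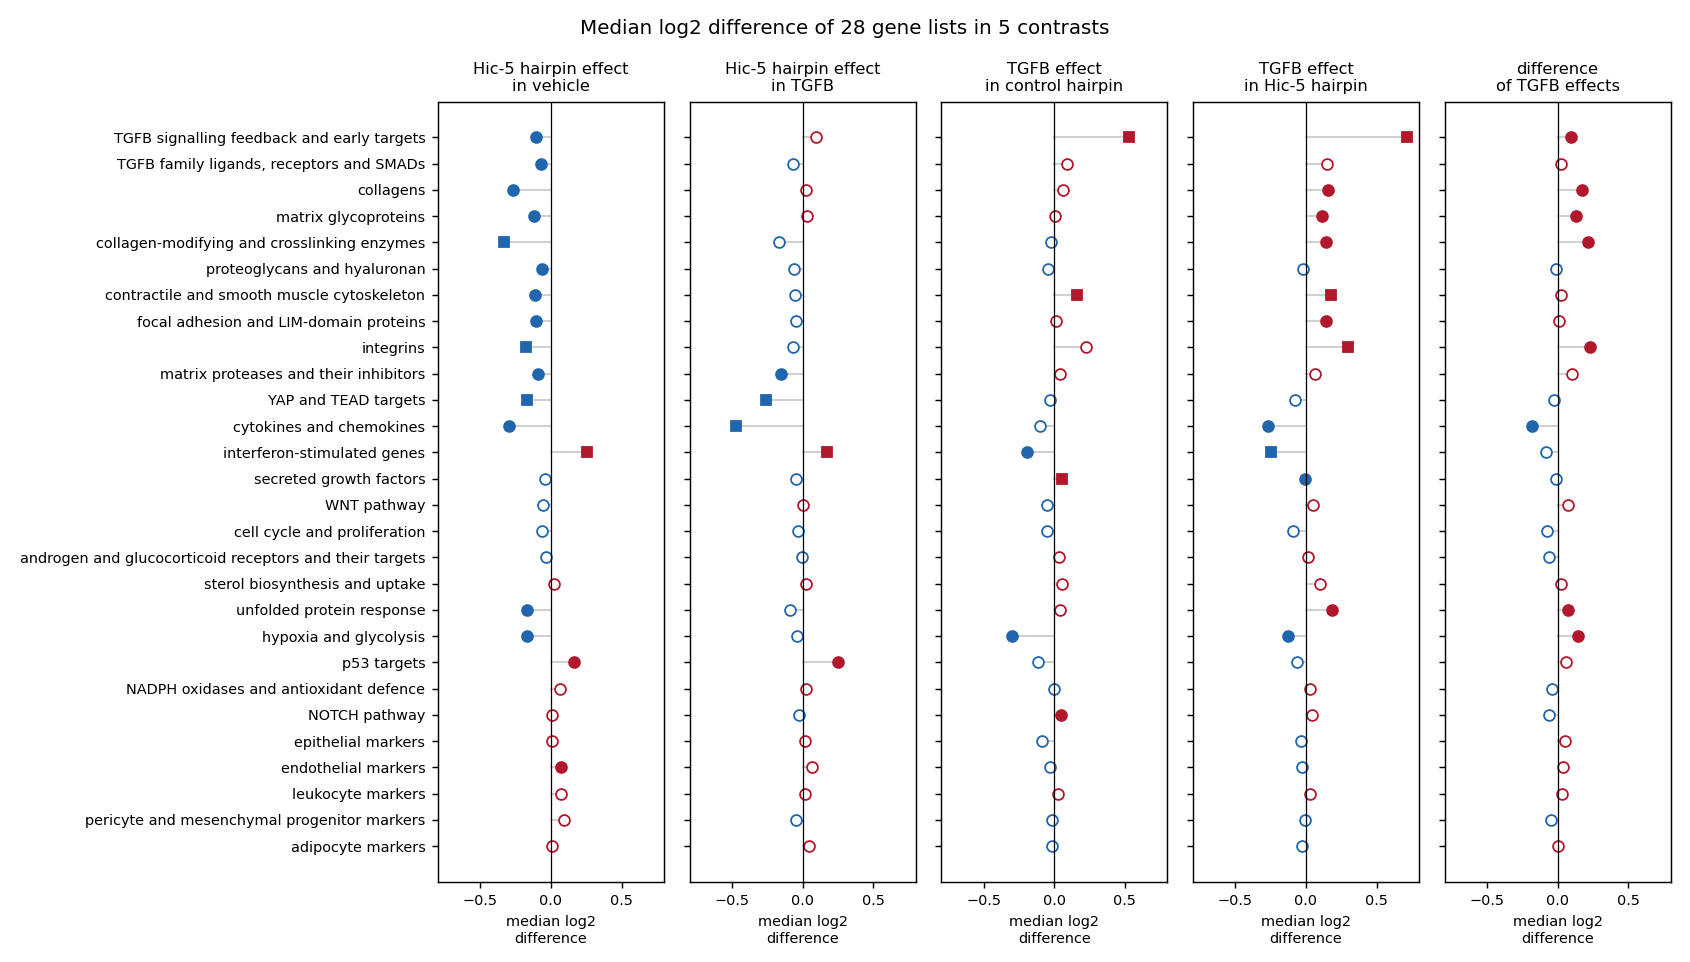
Median log2 difference (x axes) of 28 gene lists (y axis) in the 5 contrasts, red where the median is above 0 and blue where it is below. Filled marks are lists called by camera with the preset correlation, 17, 5, 6, 12 and 8 from left to right, and squares are those called with an estimated correlation too, 4, 3, 3, 4 and 0.

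In the presence of TGFB the Hic-5 hairpin line differed from the control line in 498 genes, of which 110 were higher and 388 lower. The cytokine genes stood out, with IL6 3.45-fold lower and CCL2 lower too, and the interferon-stimulated genes were again higher, with IFIT2 3.15-fold up. At a change of at least 1.5-fold there were 167 genes, 38 higher and 129 lower. The largest rises were those of IFIT2 (1.66 ± 0.26, adjusted p = 0.000797), NTS (1.55 ± 0.15, 2.33e-06), ANXA10 (1.40 ± 0.18, 9.13e-05) and IFI44 (1.39 ± 0.29, 0.00825). CYP24A1, the vitamin D 24-hydroxylase, rose by 1.24 ± 0.17 (adjusted p = 0.000136), OASL by 1.16 ± 0.17 (0.000274), the growth factor gene HGF by 1.09 ± 0.24 (0.0139) and the actin-severing gelsolin, GSN, by 0.99 ± 0.11 (2.15e-05). The largest falls were those of IL6 (-1.79 ± 0.24, adjusted p = 0.000136), CCL2 (-1.61 ± 0.12, 9.15e-08), CD24 (-1.59 ± 0.19, 3.47e-05) and CEMIP (-1.49 ± 0.25, 0.00146). CXCL8, a neutrophil chemokine, and PIEZO2 fell by 1.47 ± 0.18 and 1.47 ± 0.12 (adjusted p = 5.67e-05 and 2e-07), and PDCD1LG2, a ligand of the receptor PD-1, by 1.38 ± 0.20 (0.00024). PMEPA1, a TGFB-induced inhibitor of SMAD signalling, fell by 1.31 ± 0.12 (adjusted p = 2.33e-06) and the neuregulin gene NRG1 by 1.27 ± 0.16 (9.13e-05).

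Of the 28 lists, 5 shifted between the hairpin lines in TGFB with the preset correlation and 3 with an estimated one. Cytokines and chemokines had 13 of 27 down, 0 up and 14 not called, with 15 down and 1 up adjusted over the list alone. The median was -0.473 (camera adjusted p = 3.1e-16, and 0.0276 with an estimated correlation). LIF, a cytokine of the IL6 family, fell by 1.06 ± 0.14 (adjusted p = 8.68e-05). YAP and TEAD targets had 4 of 18 down, 0 up and 14 not called, with 9 down adjusted over the list alone. The median was -0.263 (camera adjusted p = 1e-06, and 0.0262 with an estimated correlation). CRIM1 fell by 0.58 ± 0.09 (adjusted p = 0.000356), the LIM-domain gene AJUBA by 0.48 ± 0.09 (0.0042), ANKRD1 by 0.89 ± 0.18 (0.0072) and AXL by 0.36 ± 0.09 (0.0313). The AXL call was lost without control TGFB replicate 1 (0.0905), 2 (0.0572) or 4 (0.0609), without Hic-5 TGFB replicate 2 (0.0994), 4 (0.0743) or 5 (0.0732), and in a fit of the 2 groups alone (0.0651). Interferon-stimulated genes had 7 of 24 up, 0 down and 17 not called, with 9 up adjusted over the list alone. The median was 0.173 (camera adjusted p = 1.67e-05, and 0.0276 with an estimated correlation), among them IFIT1 (1.16 ± 0.23, adjusted p = 0.00619).

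Matrix proteases and their inhibitors had 3 of 26 down, 2 up and 21 not called in TGFB, with 6 down and 4 up adjusted over the list alone. The median was -0.152 (camera adjusted p = 0.018, but adjusted p = 0.42 with an estimated correlation, 0.227 with dim genes left out and 0.0627 without control TGFB replicate 4). ADAMTS12 fell by 0.85 ± 0.11 (adjusted p = 8.68e-05) and the aggrecanase gene ADAMTS5 by 0.48 ± 0.08 (0.00143), whereas CTSK, the collagen-degrading cathepsin K, rose by 0.88 ± 0.15 (0.00185) and the protease inhibitor gene TIMP1 by 0.51 ± 0.12 (0.0199). The TIMP1 call was lost without control TGFB replicate 3 (0.0620) or 5 (0.0565) or Hic-5 TGFB replicate 1 (0.0523). The p53 targets had 1 of 21 up, 0 down and 20 not called, with 2 up and 1 down adjusted over the list alone. The median was 0.254 (camera adjusted p = 0.00231, but adjusted p = 0.42 with an estimated correlation). The gene that rose was PLK3, a stress-responsive kinase (0.55 ± 0.11, adjusted p = 0.00699).

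Outside those lists, the WNT ligand gene WNT5A fell by 1.15 ± 0.13 in TGFB (adjusted p = 2.15e-05), MYLK by 0.98 ± 0.07 (9.15e-08), THBS2 by 0.91 ± 0.10 (2.26e-05), the fibrillin gene FBN2 by 0.42 ± 0.08 (0.00501) and THBS1 by 0.78 ± 0.16 (0.00669). CHRDL1 fell by 0.92 ± 0.12 (adjusted p = 9.6e-05), INHBA, a subunit of activins, by 1.03 ± 0.18 (0.00179) and the Notch ligand gene JAG1 by 0.49 ± 0.10 (0.00664), while TEK rose by 0.83 ± 0.16 (0.00463). ACTA2 rose by 0.88 ± 0.22 (adjusted p = 0.0279), a call lost without control TGFB replicate 2 (0.0727) or 5 (0.0829) or Hic-5 TGFB replicate 1 (0.0657), 3 (0.0939) or 4 (0.0683). Collagens had 0 of 24 called in TGFB (camera adjusted p = 0.961), matrix glycoproteins 5 down (0.0928), contractile genes 1 up and 1 down (0.0519) and integrins 0 (0.595). Over all 23 lists that were not called, the camera adjusted p ran from 0.0508 to 0.987. The median, mean and test differed in sign for the TGFB feedback genes, collagens, matrix glycoproteins, the WNT pathway and the pericyte markers. Without control TGFB replicate 5, 9 lists were called, with the crosslinking enzymes (0.00991), contractile genes (0.0148), sterol genes (0.0333) and unfolded protein response (0.0148) added. Without Hic-5 TGFB replicate 4, 8 were, with the contractile genes (0.0364), unfolded protein response (0.0366) and endothelial markers (0.0448) added, and without Hic-5 TGFB replicate 5, 8 were, with the matrix glycoproteins (0.0321), contractile genes (0.0224) and unfolded protein response (0.0201) added. The unfolded protein response also passed without control TGFB replicate 3 (0.0270) or Hic-5 TGFB replicate 2 (0.0308), and with dim genes left out the proteoglycans did (0.0401).

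The 2 hairpin effects, which share no arrays, called 250 genes in common, where independent lists would share 16.2. Of these genes 56 were higher in the Hic-5 line in both treatments (1.17 for independent lists), 194 were lower in both (8.47) and 0 changed in opposite directions. Across the 18414 genes, which are not independent replicates, the hairpin effects correlated at 0.533, and leaving out each array in turn gave a jackknife standard error of 0.142 (interval 0.25 to 0.816).

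TGFB changed 1475 genes in the control hairpin line, of which 625 rose and 850 fell. NOX4, an NADPH oxidase, was 6.07-fold higher and the metallothionein gene MT1X 6.03-fold higher, while the cytokine gene IL1B was 5.36-fold lower and PTX3, the acute phase protein pentraxin 3, was lower too. The lists of TGFB feedback genes and contractile genes shifted up with either correlation of camera. At a change of at least 1.5-fold there were 481 genes, 253 up and 228 down.

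By size, NOX4 (2.60 ± 0.20, adjusted p = 5.87e-08) was followed by the metal-binding metallothioneins MT1X (2.59 ± 0.34, 2.64e-05) and MT1M (2.39 ± 0.44, 0.00106), then PMEPA1 (2.22 ± 0.12, 5.54e-10), MT1F (2.11 ± 0.29, 4.74e-05), NPR3, the natriuretic peptide clearance receptor gene (2.00 ± 0.23, 7.85e-06), TSPAN2, a tetraspanin (1.96 ± 0.20, 1.91e-06), and MT1E (1.95 ± 0.23, 8.91e-06). The largest falls were those of IL1B (-2.42 ± 0.14, adjusted p = 5.54e-10), PTX3 (-2.36 ± 0.13, 4.61e-10), the receptor tyrosine kinase gene KIT (-1.69 ± 0.15, 3.88e-07) and VCAM1, a leukocyte adhesion molecule (-1.68 ± 0.18, 3.44e-06). They were followed by PLD1, a phospholipase (-1.49 ± 0.17, adjusted p = 8.33e-06), GDF5, a ligand of the BMP group (-1.46 ± 0.17, 5.19e-06), CCN3 (-1.44 ± 0.13, 2.81e-07), the transmembrane protein gene CDCP1 (-1.44 ± 0.12, 1.15e-07) and ADM (-1.37 ± 0.13, 8.04e-07).

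TGFB feedback and early targets had 16 of 23 genes up, 0 down and 7 not called in the control line, with 17 up adjusted over the list alone. The median was 0.527 (camera adjusted p = 4.59e-20, and 0.00704 with an estimated correlation). After PMEPA1 came SMAD7, the inhibitory SMAD (1.5 ± 0.14, adjusted p = 7.33e-07), LTBP2 (1.27 ± 0.13, 1.79e-06) and the transcription factor gene BHLHE40 (0.96 ± 0.11, 4.71e-06). Contractile genes had 7 of 25 up, 1 down and 17 not called, with 10 up and 1 down adjusted over the list alone. The median was 0.158 (camera adjusted p = 4.97e-07, and 0.0149 with an estimated correlation). They included ACTC1, cardiac actin (1.27 ± 0.11, adjusted p = 1.39e-07), tropomyosin 1, TPM1 (1.27 ± 0.14, 3.39e-06), transgelin, TAGLN (0.95 ± 0.14, 8.84e-05), and PDLIM7 (0.71 ± 0.11, 0.000157). ACTA2, chosen after its values were seen, differed by -0.33 ± 0.22 (adjusted p = 0.449, but 0.0449 with a replicate block).

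Secreted growth factors had 5 of 27 up, 1 down and 21 not called after TGFB in the control line, with 7 up and 1 down adjusted over the list alone. The median was 0.0558 (camera adjusted p = 0.00717, and 0.0217 with an estimated correlation). PDGFA rose by 1.28 ± 0.10 (adjusted p = 7.29e-08), PDGFC by 1.05 ± 0.13 (1.03e-05), IGFBP7, which binds insulin-like growth factors, by 0.94 ± 0.12 (2e-05) and the EGF receptor ligand gene HBEGF by 0.67 ± 0.11 (0.000349). The NOTCH pathway had 3 of 16 up, 0 down and 13 not called, with 4 up adjusted over the list alone. The median was 0.0445 (camera adjusted p = 0.0203, but adjusted p = 0.413 with an estimated correlation, 0.0616 with dim genes left out, 0.0706 without control vehicle replicate 4 and 0.0546 without control TGFB replicate 4). The 3 were JAG1 (0.82 ± 0.10, adjusted p = 9.96e-06), the Notch target HES1 (0.96 ± 0.13, 3.23e-05) and the receptor gene NOTCH2 (0.67 ± 0.09, 4.85e-05).

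Hypoxia and glycolysis genes had 12 of 23 down, 1 up and 10 not called, with 15 down and 1 up adjusted over the list alone. The median was -0.299 (camera adjusted p = 1.38e-09, but adjusted p = 0.171 with an estimated correlation). Besides ADM, the glucose transporter genes SLC2A1 and SLC2A3 fell by 0.61 ± 0.10 and 1.09 ± 0.17 (adjusted p = 0.000258 and 0.000259) and the enolase gene ENO2 by 1.06 ± 0.18 (0.000535). Interferon-stimulated genes had 5 of 24 down, 0 up and 19 not called, with 7 down and 1 up adjusted over the list alone. The median was -0.196 (camera adjusted p = 0.00717, but adjusted p = 0.171 with an estimated correlation). The antiviral GTPase gene MX1 fell by 0.79 ± 0.14 (adjusted p = 0.000606), IFIT1 by 1.23 ± 0.23 (0.0012), IFIT3 by 1.02 ± 0.19 (0.00145) and OAS1 by 0.41 ± 0.10 (0.00888).

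The other 22 lists were not called in the control line (camera adjusted p from 0.0897 to 0.962), though several held genes that moved both ways. TGFB family genes had 10 of 29 up and 7 down (camera adjusted p = 0.219), with BMP6 up by 1.09 ± 0.13 (adjusted p = 8.33e-06), the signalling protein gene SMAD3 down by -0.78 ± 0.10 (1.58e-05), INHBA up by 1.42 ± 0.18 (1.96e-05) and BMP4 down by -1.18 ± 0.15 (2.34e-05). Cytokines and chemokines had 7 of 27 down and 2 up (camera adjusted p = 0.0930), and the 2 that rose were LIF (1.26 ± 0.14, adjusted p = 2.6e-06) and IL11 (1.11 ± 0.14, 2.67e-05). Collagens had 3 of 24 up and 1 down (0.252), with COL4A1, of the basement membrane collagen IV, up by 0.93 ± 0.11 (8.69e-06) and COL8A1 down by -0.72 ± 0.11 (0.000196). The cytokines passed without control vehicle replicate 1 (0.00425) or control TGFB replicate 3 (0.0466), and the focal adhesion genes without control vehicle replicate 2 (0.0227) or 5 (0.0477) or control TGFB replicate 3 (0.0311). The median was below 0 and the mean above 0 for the crosslinking enzymes, the proteoglycans, the YAP targets, the WNT pathway, the NADPH oxidases and the pericyte markers.

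In the Hic-5 hairpin line TGFB changed 1622 genes, of which 640 rose and 982 fell. NOX4 was 8.55-fold higher, and PTX3 and VCAM1 were 7.92-fold and 7.35-fold lower. The lists of feedback, contractile and integrin genes shifted up and that of interferon-stimulated genes shifted down with either correlation of camera. At a change of at least 1.5-fold there were 599 genes, 264 up and 335 down. After NOX4 (3.10 ± 0.20, adjusted p = 2.54e-09) the largest rises were those of TSPAN2 (2.31 ± 0.20, 1.08e-07), the kinase gene NUAK1 (2.13 ± 0.12, 3.18e-10), PRR5L, which encodes a partner of the kinase complex mTORC2 (2.12 ± 0.10, 7.74e-12), and PGM2L1, a sugar phosphate enzyme (2.10 ± 0.23, 1.44e-06). NPR3 (2.08 ± 0.23, adjusted p = 2.56e-06), the sialyltransferase gene ST6GAL2 (2.08 ± 0.15, 5.39e-09), SMAD7 (2.06 ± 0.14, 4.75e-09) and MT1X (2.05 ± 0.34, 0.000228) followed. The largest falls were those of PTX3 (-2.99 ± 0.13, adjusted p = 4.51e-12), VCAM1 (-2.88 ± 0.18, 1.67e-09), GPAT3 (-1.88 ± 0.17, 1.13e-07), IL1B (-1.78 ± 0.14, 2.62e-08) and RGS4, a regulator of G protein signalling (-1.72 ± 0.18, 1.29e-06).

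TGFB feedback and early targets had 16 of 23 up, 0 down and 7 not called in the Hic-5 line, the same counts adjusted over the list alone. The median was 0.713 (camera adjusted p = 3.85e-24, and 0.00278 with an estimated correlation). LTBP2 rose by 1.89 ± 0.13 (adjusted p = 4.24e-09), PMEPA1 by 1.46 ± 0.12 (7.84e-08) and BHLHE40 by 1.19 ± 0.11 (1.57e-07). Contractile genes had 10 of 25 up, 0 down and 15 not called, with 11 up and 1 down adjusted over the list alone. The median was 0.178 (camera adjusted p = 2.24e-07, and 0.00716 with an estimated correlation). TPM1 rose by 1.60 ± 0.14 (adjusted p = 8.37e-08), TAGLN by 1.35 ± 0.14 (6.65e-07), ACTC1 by 1.03 ± 0.11 (1.12e-06) and PDLIM7 by 0.94 ± 0.11 (3.5e-06), while ACTA2, again chosen after its values were seen, differed by -0.27 ± 0.22 (0.615). Integrins had 5 of 16 up, 1 down and 10 not called, with 7 up and 1 down adjusted over the list alone. The median was 0.297 (camera adjusted p = 0.000138, and 0.00546 with an estimated correlation). The beta subunit genes ITGB3 and ITGB5 rose by 1.00 ± 0.13 and 0.84 ± 0.11 (adjusted p = 2.01e-05 and 2.08e-05) and the collagen receptor gene ITGA11 by 0.79 ± 0.13 (0.00034). Focal adhesion genes had 8 of 26 up, 2 down and 16 not called, with 9 up and 4 down adjusted over the list alone. The median was 0.141 (camera adjusted p = 0.000443, but adjusted p = 0.189 with an estimated correlation). The scaffold gene NEDD9 rose by 1.58 ± 0.12 (adjusted p = 6.96e-09) and the LIM-domain gene FHL3 by 0.77 ± 0.10 (1.69e-05).

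Collagens had 9 of 24 up, 2 down and 13 not called after TGFB in the Hic-5 line, with 9 up and 3 down adjusted over the list alone. The median was 0.158 (camera adjusted p = 4.88e-05, but adjusted p = 0.202 with an estimated correlation). COL4A1 rose by 1.35 ± 0.11 (adjusted p = 3.76e-08), COL5A1 by 1.16 ± 0.15 (1.38e-05) and COL4A2 by 0.76 ± 0.12 (9.79e-05). Matrix glycoproteins had 8 of 25 up, 3 down and 14 not called, with 9 up and 3 down adjusted over the list alone. The median was 0.112 (camera adjusted p = 2e-04, but adjusted p = 0.189 with an estimated correlation). FBLN5, an elastic fibre protein, rose by 1.48 ± 0.11 (adjusted p = 9.89e-09), THBS1 by 1.93 ± 0.16 (3.76e-08) and TNC by 1.48 ± 0.14 (4.6e-07). The crosslinking enzymes had 4 of 17 up, 0 down and 13 not called, with 5 up adjusted over the list alone. The median was 0.141 (camera adjusted p = 0.000241, but adjusted p = 0.183 with an estimated correlation), led by LOX (1.15 ± 0.12, adjusted p = 1.1e-06) and P4HA3, a collagen prolyl hydroxylase (0.93 ± 0.10, 2.53e-06). Hic-5 vehicle replicate 2, on the vehicle side of this comparison, had the highest mean of its group over the collagens and the matrix glycoproteins.

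Cytokines and chemokines had 10 of 27 down, 3 up and 14 not called in the Hic-5 line, with 12 down and 4 up adjusted over the list alone. The median was -0.271 (camera adjusted p = 3.62e-05, but adjusted p = 0.189 with an estimated correlation). Besides VCAM1 and IL1B, the chemokine gene CXCL1 fell by 1.31 ± 0.16 (adjusted p = 5.72e-06), while IL11 rose by 1.70 ± 0.14 (6.8e-08). Interferon-stimulated genes had 7 of 24 down, 0 up and 17 not called, with the same counts adjusted over the list alone. The median was -0.249 (camera adjusted p = 3.62e-05, and 0.0279 with an estimated correlation). OAS1 and OAS2, antiviral enzymes, fell by 0.67 ± 0.10 and 0.64 ± 0.11 (adjusted p = 4.86e-05 and 0.000558), MX1 by 0.70 ± 0.14 (0.00151) and IFIT1 by 1.14 ± 0.23 (0.00193). Hypoxia and glycolysis genes had 8 of 23 down, 1 up and 14 not called, with 10 down and 1 up adjusted over the list alone. The median was -0.125 (camera adjusted p = 0.000138, but adjusted p = 0.297 with an estimated correlation). BNIP3, a hypoxia-induced mitophagy gene, fell by 1.27 ± 0.19 (adjusted p = 9.76e-05), ADM by 0.87 ± 0.13 (0.00011) and SLC2A3 by 1.13 ± 0.17 (0.000114).

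Secreted growth factors had 6 of 27 up, 1 down and 20 not called in the Hic-5 line, with 8 up and 3 down adjusted over the list alone. Their median was -0.00524 while the mean (0.137) and the test pointed up (camera adjusted p = 0.0268, but adjusted p = 0.0667 with an estimated correlation, 0.0622 without Hic-5 vehicle replicate 2, 0.0505 without Hic-5 TGFB replicate 4 and 0.0592 without both vehicle arrays numbered 2). PDGFA rose by 1.47 ± 0.10 (adjusted p = 4.75e-09) and IGFBP7 by 1.00 ± 0.12 (5.29e-06). Unfolded protein response genes had 2 of 24 up, 1 down and 21 not called, with 5 up and 1 down adjusted over the list alone. The median was 0.185 (camera adjusted p = 0.00853, but adjusted p = 0.297 with an estimated correlation). The 2 were HSPA5, the main chaperone of the endoplasmic reticulum (0.29 ± 0.08, adjusted p = 0.0187), and HERPUD1 (0.34 ± 0.09, 0.0189). The HSPA5 call was lost without Hic-5 vehicle replicate 1 (0.0503) or 3 (0.0533) or Hic-5 TGFB replicate 5 (0.0604) and in a fit of the 2 groups alone (0.0642), and the HERPUD1 call without Hic-5 vehicle replicate 3 (0.0659) or 4 (0.0594) or Hic-5 TGFB replicate 4 (0.0551) or 5 (0.0590) and in a fit of the 2 groups alone (0.0553). The other 16 lists were not called (camera adjusted p from 0.0613 to 0.806), and for the proteoglycans the median was below 0 and the mean above 0. Among them, TGFB family genes passed without Hic-5 vehicle replicate 1 (0.0366) or 5 (0.0401), Hic-5 TGFB replicate 3 (0.0116) or the dim genes (0.0313), and cell cycle genes without Hic-5 vehicle replicate 1 (0.0366) or 2 (0.0217) or Hic-5 TGFB replicate 4 (0.0210). Without Hic-5 vehicle replicate 2 the WNT pathway (0.0226) and the NOTCH pathway (0.0469) passed too.

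The TGFB effects of the lines, which share no arrays, called 927 genes in common, where independent lists would share 130. Of these 399 rose in both (21.7 for independent lists), 528 fell in both (45.3) and 0 changed in opposite directions, and the effects correlated at 0.755 across the 18414 genes. The size of the response was compared over the 2873 genes called for the mean of the TGFB effects of the 2 lines, 1107 up and 1766 down. The median rise was 0.40 in the control line and 0.38 in the Hic-5 line, and the median fall was -0.33 and -0.34. The root mean square response of the Hic-5 line was 1.10 times that of the control line, with a jackknife interval of 0.972 to 1.23 that included equal responses.

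**Figure D4:**
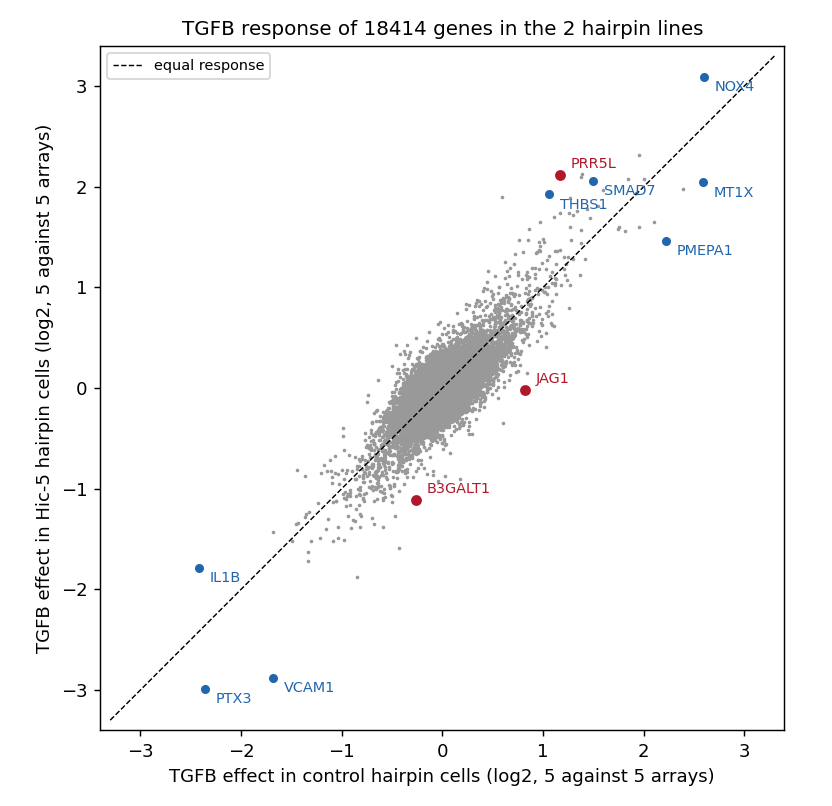
TGFB effect on each of 18414 genes (points) in the control hairpin line (x axis, log2) and in the Hic-5 hairpin line (y axis, log2), 5 against 5 arrays each; the dashed line marks equal effects. The 3 genes called for a difference, PRR5L, JAG1 and B3GALT1, are in red and other named genes in blue, and the effects correlated at 0.755.

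Whether the hairpin altered the TGFB response was tested per gene as the difference of TGFB effects. With limma 3 of 18414 genes were called, 1 with a higher and 2 with a lower response in the Hic-5 line (1 and 1 after cyclic loess). At an unadjusted p under 0.05 there were 880 genes (4.78%). PRR5L responded more in the Hic-5 than the control line (2.12 against 1.17, difference 0.95 ± 0.14, adjusted p = 0.0142). It was called in 20 of 20 fits without 1 array (adjusted p from 0.00907 to 0.0473). TGFB changed JAG1 by 0.82 in the control line and -0.02 in the Hic-5 line (difference -0.84 ± 0.14, adjusted p = 0.0321). In vehicle its arrays were already higher in the Hic-5 line (7.51 to 7.75 against 7.07 to 7.45). B3GALT1, a galactosyltransferase gene, differed by -0.26 and -1.12 (difference -0.85 ± 0.14, adjusted p = 0.0321).

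The calls of JAG1 and B3GALT1 rested on all arrays. JAG1 was called in 3 of the 20 fits without 1 array. The call was lost without control vehicle replicate 1 (adjusted p = 0.0594), 2 (0.0738), 3 (0.0872) or 4 (0.0729), Hic-5 vehicle replicate 1 (0.0617), 2 (0.0837), 3 (0.105), 4 (0.0915) or 5 (0.0907), control TGFB replicate 1 (0.0569), 2 (0.101), 3 (0.0776), 4 (0.102) or 5 (0.0882) or Hic-5 TGFB replicate 2 (0.103), 3 (0.0609) or 4 (0.0739). B3GALT1 was called in 3 as well. Its call was lost without control vehicle replicate 1 (0.0594), 2 (0.0738), 3 (0.0550), 4 (0.0729) or 5 (0.0744), Hic-5 vehicle replicate 1 (0.0803), 2 (0.0837), 4 (0.0915) or 5 (0.0907), control TGFB replicate 1 (0.0635), 2 (0.101), 4 (0.0919) or 5 (0.0882) or Hic-5 TGFB replicate 2 (0.103), 3 (0.0929), 4 (0.0543) or 5 (0.0726). For JAG1 and B3GALT1 adjusted p was 0.119 and 0.147 without both vehicle arrays numbered 2, and 0.0734 and 0.0677 with the replicate block. For B3GALT1 it was 0.0705 after cyclic loess and 0.0541 with array weights.

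Other genes with large differences were not called. The TGFB effect on PMEPA1 differed by -0.76 ± 0.18 (adjusted p = 0.410), that on VCAM1 by -1.20 ± 0.26 (0.301) and that on THBS1 by 0.87 ± 0.22 (0.602). For SMAD7 the difference was 0.56 ± 0.20 (adjusted p = 0.994), for LTBP2 0.62 ± 0.18 (0.846), for TNC 0.71 ± 0.20 (0.790) and for IL6 -0.48 ± 0.34 (0.994), and these 4 genes were chosen after their values were seen. With the component score as a covariate, added after the data were seen, VCAM1 and ITGB5 passed (adjusted p = 0.0228 and 0.0496).

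Of the 28 lists, 8 shifted in the difference by camera with its preset correlation, and 0 did with an estimated correlation. Collagens shifted up (median 0.175, camera adjusted p = 6.78e-05, but adjusted p = 0.476 with an estimated correlation), as did matrix glycoproteins (0.134, 6.78e-05, but adjusted p = 0.354 with an estimated correlation) and crosslinking enzymes (0.212, 0.000497, but adjusted p = 0.354 with an estimated correlation). Of the members of these lists 0 were called over all genes, and adjusted over the list alone 5 glycoproteins were, all up. The members with the smallest p included COL4A2 (0.45 ± 0.16, adjusted p = 0.994) and P4HA3 (0.43 ± 0.15, 0.986). Integrins shifted up (0.227, camera adjusted p = 0.00839, but adjusted p = 0.114 with an estimated correlation and 0.0521 without Hic-5 vehicle replicate 2), with ITGB5 at 0.60 ± 0.16 (adjusted p = 0.660) and 1 gene up adjusted over the list alone. Cytokines and chemokines shifted down (-0.181, camera adjusted p = 0.00388, but adjusted p = 0.668 with an estimated correlation and 0.120 without control vehicle replicate 1), with 3 genes down and 2 up adjusted over the list alone.

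Hypoxia and glycolysis genes shifted up in the difference (median 0.145, camera adjusted p = 0.00513, but adjusted p = 0.668 with an estimated correlation, 0.148 without control vehicle replicate 2 and 0.107 without both vehicle arrays numbered 2), with ADM at 0.50 ± 0.19 (adjusted p = 0.994). TGFB feedback genes shifted up (0.0949, camera adjusted p = 0.0256, but adjusted p = 0.668 with an estimated correlation), with 2 up and 1 down adjusted over the list alone. That list was no longer called without control vehicle replicate 2 (0.154), Hic-5 vehicle replicate 3 (0.0790) or 4 (0.160), control TGFB replicate 1 (0.0518), 2 (0.0777) or 4 (0.0549) or Hic-5 TGFB replicate 4 (0.104). The unfolded protein response list shifted up (0.0709, camera adjusted p = 0.0468, but adjusted p = 0.668 with an estimated correlation and 0.0959 without both vehicle arrays numbered 2), with DDIT4, a stress-induced inhibitor of mTORC1, at 0.72 ± 0.25 (adjusted p = 0.986). It was lost without control vehicle replicate 1 (0.0728), 2 (0.154), 3 (0.0746) or 4 (0.0691), Hic-5 vehicle replicate 2 (0.0521), 3 (0.123) or 4 (0.0698), control TGFB replicate 1 (0.0522), 3 (0.0856) or 4 (0.0887) or Hic-5 TGFB replicate 1 (0.0743), 2 (0.112), 4 (0.120) or 5 (0.215). Without control vehicle replicate 2, 5 lists were called in place of 8. The other 20 lists had camera adjusted p from 0.0973 to 0.884, and the median and the mean differed in sign for the proteoglycans, the NADPH oxidases and the endothelial, leukocyte and adipocyte markers.

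The last comparison asked whether the genes moved by the Hic-5 hairpin in vehicle were those moved by TGFB in the control line. Among the genes called in both, 74 were lower with the hairpin and rose with TGFB (13.6 for independent lists) and 46 were higher with the hairpin and fell with TGFB (9.05). In the same direction, 61 were lower in both (18.6) and 11 were higher in both (6.65). LTBP2 was lower with the hairpin and rose with TGFB, and CCN3, IL1B and ADM were lower in both. Across genes the effects correlated at 0.0888, with a jackknife interval of -0.282 to 0.459. The control vehicle arrays stand in both comparisons. In 50 simulations of unchanged groups against them, which leave out any pairing of the vehicle arrays, correlations ran from -0.483 to 0.916 (mean 0.48) and the covariance averaged 0.0126. The observed covariance was 0.00409, against 0.00691 from shared arrays with pairing assumed. With whole pairs of vehicle arrays split between the comparisons the correlation was -0.049 on average (from -0.127 to 0.0169 over 10 splits).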

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

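Of the tests in this part, those on gene span and on a batch shared by the arrays numbered 2 were chosen only after the result was seen.

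Within each group of 5 arrays, the highest or lowest array was examined for a gap to its nearest neighbour above 0.71 of the group's range, for 135 genes, 28 list means and the quality measures. Of 664 groups tested 61 passed (9.19%), and chance flags about 1 in 20. Control vehicle replicate 2 accounted for 11 of them, control TGFB replicate 5 for 10, Hic-5 TGFB replicate 3 for 8 and Hic-5 vehicle replicate 2 for 7.

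On the main component, control vehicle replicate 2 (gap 0.790 of the range), Hic-5 vehicle replicate 2 (0.745) and Hic-5 TGFB replicate 3 (0.719) were highest. Mean correlation with the own group was 0.978 for control vehicle replicate 2 (gap 0.883 of the range), 0.987 for control TGFB replicate 5 (gap 0.747) and 0.989 for Hic-5 TGFB replicate 3 (gap 0.814), each the lowest of its group. Uneven recovery of long transcripts stays open: the deviations of the vehicle arrays numbered 2 fell with gene span, with Spearman rho -0.235 in the weaker of the pair, but so did those of control TGFB replicate 4 (-0.303) and Hic-5 TGFB replicate 3 (-0.296). A swap is argued against, since 92.5% of 40 genes placed both arrays with their own labels, and so is a batch shared by all 4 arrays numbered 2, since the lowest of the correlations between vehicle and TGFB arrays was -0.169. A batch shared by the vehicle arrays numbered 2 alone, whose deviations correlated at 0.873, stays open, and so does a biological difference between cultures, which was not tested.

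Among genes in control vehicle, replicate 2 was apart for TGFB1I1 (high, 0.768), PDLIM7 (high, 0.804), PLK3 (high, 0.712), PDCD1LG2 (low, 0.794) and TSPAN2 (low, 0.861), and replicate 5 for ACTA2 (low, 0.827), CHRDL1 (low, 0.726), PRRX1 (low, 0.769) and PTX3 (high, 0.821). In Hic-5 vehicle, replicate 1 was apart for CCL2 (low, 0.714) and PRRX1 (high, 0.857), replicate 4 for RGS4 (low, 0.727), and replicate 5 for ADM (low, 0.749) and CXCL8 (high, 0.912). Replicate 2 of that group was high for COL5A1 (0.842), PXN (0.715), SLC2A1 (0.794) and TAGLN (0.788).

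In control TGFB, replicate 1 was apart for AXL (high, 0.717), COL8A1 (low, 0.765), IL1B (low, 0.746) and IL6 (low, 0.895), replicate 3 for PRRX1 (high, 0.754) and replicate 4 for IGFBP7 (high, 0.890). Replicate 5 of that group was high for IFI44L (0.729), LOX (0.723), NEDD9 (0.715), PDIA6 (0.737), PDLIM5 (0.864) and TSPAN2 (0.784) and low for CCN1 (0.720) and PLK3 (0.732). In Hic-5 TGFB, replicate 3 was low for HSPA5 (0.795), NRG1 (0.867), PDIA6 (0.727), PGM2L1 (0.853) and TES (0.774), and replicate 4 was high for CTSK (0.71) and KIT (0.772). Replicate 5 was low for GDF5 (0.713), HES1 (0.885) and SMAD7 (0.793) and high for ITGA11 (0.780).

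Among list means, control vehicle replicate 2 was high for TGFB feedback genes (0.816), epithelial markers (0.818) and endothelial markers (0.723) and low for integrins (0.854), and replicate 5 of that group was high for the androgen and glucocorticoid list (0.836). Hic-5 vehicle replicate 2 was high for collagens (0.738) and matrix glycoproteins (0.894), replicate 4 low for the androgen and glucocorticoid list (0.805) and replicate 5 high for YAP targets (0.767). Control TGFB replicate 1 was low for cytokines (0.742), control TGFB replicate 5 low for epithelial markers (0.763) and Hic-5 TGFB replicate 3 low for the unfolded protein response (0.822).

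The TGFB effect differed between the hairpin lines for PRR5L (0.95), JAG1 (-0.84) and B3GALT1 (-0.85). By camera with its preset correlation it differed for 8 lists, with medians of 0.0949 for TGFB feedback genes, 0.175 for collagens, 0.134 for matrix glycoproteins, 0.212 for crosslinking enzymes, 0.227 for integrins, -0.181 for cytokines, 0.0709 for the unfolded protein response and 0.145 for hypoxia genes, and with an estimated correlation for 0.

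Among the 11863 rows with no single gene, which entered no comparison, 50 were called for the hairpin in vehicle, 26 for the hairpin in TGFB, 78 for TGFB in the control line and 114 for TGFB in the Hic-5 line. These are 0.421%, 0.219%, 0.658% and 0.961% of the rows, against 3.25%, 2.70%, 8.01% and 8.81% of the genes.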

How the results depend on the processing

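Leaving out both vehicle arrays numbered 2, the component score as a covariate and the replicate block within the vehicle arrays were chosen only after the result was seen. The score is taken from the same data, so it shrinks the residual spread by construction. No result changed direction past its threshold under any alternative run. The cause of the changes below was not tested, except that fits with fewer arrays have less power.

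TGFB1I1 after TGFB in the control line passed the test with the replicate block (0.43), dim genes left out (0.43), cyclic loess (0.46), array weights (0.57), without both vehicle arrays numbered 2 (0.51) and with the component score (0.52). Genes called for the hairpin in TGFB numbered 826 with array weights and 1134 with the component score, and for the hairpin in vehicle 341 in a fit of the 2 groups alone and 1198 with the component score. With that score TGFB called 2358 genes in the control line and 2711 in the Hic-5 line. For the difference, 1 gene was called over all deposited rows, 5 with array weights, 1 without both vehicle arrays numbered 2 and 10 with the component score (9 at 1.5-fold). The hairpin effects correlated at 0.372 over all deposited rows. With an estimated correlation 4, 3, 3, 4 and 0 lists were called in the 5 contrasts, and with the component score 8 were for the hairpin in TGFB.

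Without 1 array, the hairpin in vehicle called 397 to 612 genes (188 to 255 at 1.5-fold), the hairpin in TGFB 342 to 437 (147 to 176), TGFB in the control line 1126 to 1534 (447 to 529), TGFB in the Hic-5 line 1263 to 1509 (547 to 633) and the difference 1 to 3 (1 to 3). TGFB1I1 ranged from -0.96 to -0.80 and -0.92 to -0.74 for the hairpin, 0.34 to 0.52 and 0.45 to 0.56 for TGFB and -0.04 to 0.15 for the difference. Lists called ranged from 13 to 17, 4 to 9, 5 to 8, 12 to 14 and 5 to 8. The response ratio ranged from 1.06 to 1.13, the correlation of the hairpin effects from 0.409 to 0.573 and that of hairpin with TGFB from -0.0103 to 0.219.

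The main fit held no pairing. The vehicle arrays were taken as pairs only in the block below, in the splits and in the check of shared arrays. With the replicate block within these arrays alone, the hairpin in vehicle called 820 genes (280 up and 540 down) and 251 at 1.5-fold, and no call changed among TGFB1I1, 61 named genes and 28 lists. In the other comparisons pairing is not settled. Over all groups 14 of 30 pairs of equal number correlated above 0.1 (from -0.42 to 0.873). Of 20 arrays 10 correlated best with their own number. The arrays numbered 5 correlated at 0.269 to 0.616 in all groups. With the replicate block over all 20 arrays 721, 566, 1845, 1756 and 2 genes were called, 0 of 140 list results changed, and ACTA2 after TGFB in the control line passed (0.0449). JAG1 and B3GALT1 did not.

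Of the 217 named gene results, 213 kept their side of the threshold with the component score, 215 with array weights, 215 after cyclic loess, 216 with the mean of rows, 216 with trend and robust moderation and 212 without both vehicle arrays numbered 2. With dim genes left out 193 of 193 did, in the fit of the 2 groups alone 191 of 200, and without 1 array 2247 of 2340, where 91 calls were lost and 2 gained. Cyclic loess moved the share of falls among called genes from 67.2% to 65.2% for the hairpin in vehicle and from 77.9% to 71.3% in TGFB. For TGFB it moved from 57.6% to 50.8% in the control line and from 60.5% to 53.2% in the Hic-5 line, and for the difference from 66.7% to 50%. In the control line 784 genes rose and 809 fell after cyclic loess, and 724 rose and 734 fell without both vehicle arrays numbered 2.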

Other observations

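Of the tests in this part, the share of the interferon-stimulated shift kept in TGFB, the count of glucocorticoid list members that went either way and the splits that part the vehicle pairs were chosen only after the result was seen.

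Genes of the metallothioneins, small metal-binding proteins, were mostly higher after TGFB. The 13 measured, with the pseudogenes MT1DP, MT1IP and MT1JP included, had a median log2 effect of 1.12 in the control line and 1.03 in the Hic-5 line. Beside MT1X (2.59 and 2.05), MT1M (2.39 and 1.98), MT1F (2.11 and 1.65) and MT1E (1.95 and 1.60), the effects were 1.75 and 1.60 for MT1G, 1.18 and 1.03 for MT1JP and 1.12 and 1.03 for MT1DP. MT2A, a widely expressed member, gave 0.92 and 0.97. MT3, whose mean of 6.04 lay close to the median of 5.98 over all genes, gave 0.02 and 0.04. The family was singled out after its values were seen.

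Glucocorticoid receptor activity, which also induces metallothioneins, stays open: the other 17 members of the androgen and glucocorticoid list had median effects of 0.0181 and 0.0119, but the bound of 0.1 set for them was wrong, since 3 members rose and 4 fell in both lines. TSC22D3 and CRISPLD2 rose (0.584 and 0.81 in the control line, 0.454 and 0.56 in the Hic-5 line), while DUSP1, ERRFI1 and CEBPD fell (-0.466, -0.593 and -0.737, and -0.377, -0.862 and -0.724). A load of zinc or another metal may contribute: SLC30A1, the zinc exporter gene induced by metals, rose by 0.946 in the control line (adjusted p = 0.000732), and its value of 0.467 in the Hic-5 line did not pass (adjusted p = 0.0993). Signal shared between near-identical members stays open, since the lowest effect among 6 bright members was 0.921, and arrays cannot separate members that share probe sequence. Whether TGFB itself induces the family was not tested apart from these.

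Interferon-stimulated genes were higher in the Hic-5 line, and the 2 vehicle arrays that stand apart do not account for it (median without them 0.27 against 0.252, camera adjusted p = 3.93e-10). A response to the hairpin RNA could not be separated from loss of Hic-5 with 1 hairpin line per arm. The RNA sensor gene RIGI differed by 0.561 (adjusted p = 0.365). IFNB1 (-0.134, 0.703) was too dim to judge (mean 2.45 in control vehicle). Weaker basal TGFB signalling may contribute, since the list shifted down after TGFB, though in the control line adjusted p = 0.171 with an estimated correlation (0.0279 in the Hic-5 line). The median in TGFB was 68.4% of that in vehicle, and the TGFB effects on the list did not differ by the test (camera adjusted p = 0.241). Neither is decided here.

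Arrays were regrouped in 100 splits per contrast, the real one included. With pairing by number assumed, the 16 splits that part all 5 pairs are too few for a share under 0.05. Of them 1, the real one, called 598 genes and the highest other 0. Splits that parted 3 pairs called up to 11 genes and those that parted 1 called 0. If arrays do not pair, which is not settled, chance can be excluded for the other simple contrasts. For the hairpin in TGFB the real split called 498 genes and the highest other 0. For TGFB in the control line it was 1475 against 337, and in the Hic-5 line 1622 against 3. For the difference, of 100 splits that part all 5 vehicle pairs 1, the real one, called as many as 3 genes and the highest other 1. The real count fell to 1 in 15 of 20 fits without 1 array, so chance is not excluded for the count. Of 100 splits that ignore the pairs 2 called at least 3, and the other called 2049. That split put the array of each group with the highest component score on the same side, so it points to a structure of the samples.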
